A study of Mus musculus with 10 samples.

How the data were processed

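Flank B78 tumours of 5 treatment groups were measured by droplet-based single-cell RNA sequencing of transcript 5' ends and by sequencing of the TCR chains, with 3 mice pooled per group and 1 library per group and assay, 10 libraries in all. Per the labels, tumours were digested for 40 minutes, leukocytes were enriched on a density gradient, the loaded cells were CD45+, and viability was above 90%. The submitters' processing notes name Cell Ranger 7.2.0 and the mouse build mm10. The deposited matrices hold raw UMI counts per gene and cell barcode for 32285 features, without normalization, and only barcodes that the authors' software called as cells. The deposited clonotype tables give the count of cells per clonotype and a proportion, the fraction of the library's cells with a clonotype, and the proportions equal the counts divided by their total. Of the features, 78 symbols occur more than once, and genes were therefore read by identifier.

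Barcodes were kept with at least 300 genes and at most 10% mitochondrial UMIs. Doublets were scored in each library against simulated doublets and removed above an automatic threshold (scikit-image 0.26.0), or, where that threshold would have removed under 0.5% of barcodes, at a fixed 0.008 per 1000 barcodes. The percentages removed were 0.615% in ICI, 10.7% in EBRT, 12.1% in 90Y (by the fixed share), 4.80% in 177Lu and 1.82% in 225Ac, against 21.7%, 15.9%, 12.1%, 17.2% and 11.0% expected from the loading. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 20 nearest neighbours gave Leiden clusters at resolution 1 (igraph 0.11.9, leidenalg 0.10.2). A cluster took the class with the highest mean marker ratio to the 25th percentile of all clusters, if at least 3 of its fixed markers passed 20 CPM and a ratio of 1.5 and its 10 leading genes did not point to another class. Clusters of under 1000 CPM of the nuclear transcript Malat1 (barcodes low in nuclear RNA) and leukocyte clusters of over 100 CPM of the melanoma gene Sox10 or under 100 CPM of the leukocyte gene Ptprc were left without a class, by thresholds set after the data were seen. T and NK clusters were clustered again as a pool, in which a sub-cluster needed 50 cells and a lead of 0.75 (log2) over the next class, also set after the data were seen. Class names stand for cells that resemble the class by transcripts. NK cells, CD4 T cells and dendritic cells were counted but their gene levels are not reported here, although mature dendritic cells numbered over 100 in ICI, 177Lu and 225Ac.

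UMIs were summed per library and class where both libraries held at least 100 cells, and levels are given as CPM, counts scaled to the same total, of all UMIs of the class. Ratios have exact 95% intervals from the binomial distribution of one count given the sum of both, shares have exact Clopper-Pearson intervals, and ratios of shares have intervals of the same conditional kind. All cover counting error only. With 1 library per group, no test across groups and no p-value was computed, and cells were not treated as replicates. A level was called higher or lower by a size rule, a ratio of 1.5 or more, or its inverse, with an interval that excludes 1. A share needed the same ratio and intervals of both shares that do not overlap. A count of 0 was set to a floor of 3 UMIs per class sum for a bound. The 21 gene lists, holding 280 different genes of which 3 are missing from the features, were fixed before the data were examined, as were the groups, the 10 comparisons, the cell filter, the size rule, the named-gene rule and 18 alternatives. They cover responses to type I interferon and interferon gamma, MHC class I and class II presentation, cytotoxic effectors, inhibitory receptors and exhaustion, stem-like and memory T cells, tissue residency, T cell costimulation, Treg effectors, proliferation, the p53 and DNA damage response, cGAS-STING components, inflammatory macrophages, immunosuppressive and repair macrophages, chemokines, checkpoint ligands, hypoxia and glycolysis, immediate early and dissociation stress genes, and melanoma and erythroid transcripts as background. A list's value is the median log2 ratio of its members with at least 20 UMIs in the library where they are higher, placed among 10000 random lists of the same size matched over 20 bins of level. Of 461 list medians and 162 share ratios computed, 116 and 28 are reported here. This set was narrowed after a first look at how all of them varied with the processing. Levels of some genes of the lists and of the named-gene rule are not reported here.

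Named genes are members of these lists and genes given by a rule. For each comparison of a radiation group with ICI and each of CD8 T, Treg and macrophage classes, the rule takes the 4 highest and 4 lowest log2 ratios among genes with at least 100 UMIs and 50 CPM in the library where they are higher, whose level is at least 20% of that in the class where the gene is highest. For macrophages of an NM600 form against EBRT it takes 3 per direction. It leaves out mitochondrial, ribosomal, haemoglobin, immune receptor, sex-linked and provisionally named genes. Which list members are quoted as examples was chosen after their values were seen. In tests on simulated data, 200 genes of a class sum were changed by 1.5-fold, 2-fold or 4-fold and recovered through the same steps. A single Poisson draw was made per comparison. In it 1.44% of unchanged genes passed the size rule in macrophages of 225Ac against ICI, 3.37% in Treg of EBRT and 3.10% in CD8 T cells of 90Y. The draws held counting noise alone, so these percentages leave out variation between pools.

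TCR diversity was computed from the deposited clonotypes, drawn 1000 times to 617 cells, the smallest library, or to 560 cells for merged and 357 for paired clonotypes. Expanded means 2 or more cells. TCR cells were not joined to RNA barcodes, because the clonotype tables hold no barcodes.

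Alternatives fixed before the data were seen were a stricter filter (500 genes, 5% mitochondrial UMIs), doublets put back or removed at a fixed share of 0.008 per 1000 barcodes in every library (called equal doublet removal), Leiden resolutions 0.5 and 2, and marker gates on cells thinned to 1000 UMIs. For levels and lists they were TMM factors (edgeR 4.0.16, R 4.3.3) and equal weight per cell, for levels alone totals without mitochondrial, ribosomal and receptor genes and doublets kept, and for lists alone members with at least 100 UMIs or with at least 1 UMI and 0.5 added. TMM factors lay between 0.969 and 1.04. For TCR they were paired clonotypes, clonotypes merged by TRB junction, no drawing, and expansion from 3 cells. After seeing the data 14 more were added, among them, for lists, equal doublet removal and the reduced totals, and a mitochondrial limit of 25% with added cells classed by their neighbours, denominators without barcodes low in nuclear RNA or of leukocytes alone, clustering without the EBRT and 90Y libraries, single macrophage clusters, and the pool without its Lef1-led sub-cluster. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.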

Results

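Cells were profiled by single-cell RNA sequencing from flank B78 melanomas of C57BL/6 mice, with T cell receptor (TCR) sequencing of the same suspensions. B78 is a line derived from B16 melanoma. By the labels CD45+ leukocytes were isolated before loading, so shares of kept barcodes reflect that step as well as the tumour. Each of the 5 groups received checkpoint blockade (ICI), antibodies against CTLA4 and PD-L1 on days -3, 0 and 3. One group received ICI alone. The other groups also received radiation, labelled as 2 Gy on day 1, from external beam radiation (EBRT) or from NM600, an alkylphosphocholine taken up by many tumours, carrying 90Y, 177Lu or 225Ac. The time over which each source delivered this dose was not compared. The isotopes 90Y and 177Lu emit beta particles, and 225Ac emits alpha particles. Tumours were harvested on day 15, and 3 mice were pooled per group into 1 RNA and 1 TCR library, so that no value below has a replicate. Intervals cover counting error only, no test between groups was possible, and every difference between libraries is also a difference between pools handled separately. The 4 comparisons with ICI alone share the ICI library and are not independent of each other.

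The deposited matrices held 139362819 UMIs for ICI, 108868072 for EBRT, 119508629 for 90Y, 181680920 for 177Lu and 96546794 for 225Ac. Mitochondrial transcripts, a sign of damaged cells, took a median of 5.79% of the UMIs of a barcode in ICI, 33.2% in EBRT, 14.5% in 90Y, 5.54% in 177Lu and 4.94% in 225Ac. After filtering and removal of doublets, 19236, 4380, 5547, 13516 and 9782 barcodes were kept, with medians of 1746, 17071, 14795, 6395.5 and 2801 UMIs. The filter passed 71.4% of the ICI barcodes and 24.7% of the EBRT barcodes, with 41.8%, 66.2% and 72.7% for 90Y, 177Lu and 225Ac. Barcodes low in nuclear RNA, which no class was given, made up 57.6% of the kept ICI barcodes and 2.33%, 7.05%, 24.8% and 28.7% of the others in the same order, a grouping set after the data were seen. Among them, 3 clusters with all 10 macrophage markers held 3048, 2205 and 1930 barcodes in ICI and 11, 4 and 4 in EBRT. The macrophage class therefore leaves out most barcodes with macrophage transcripts in ICI. A cluster of melanoma transcripts with F13a1, left without a class because its leading genes held more monocyte than melanoma markers, held 1.02%, 14.1%, 10.98%, 3.77% and 4.04%. Unnamed T and NK sub-clusters took 3.81%, 2.51%, 3.35%, 6.02% and 8.82%, and other unnamed clusters took 2.53%, 2.33%, 2.04%, 3.73% and 2.84%. T and NK sub-clusters that carried macrophage transcripts took 1.58%, 0.685%, 1.03%, 2.10% and 1.26%.

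**Figure D1:**
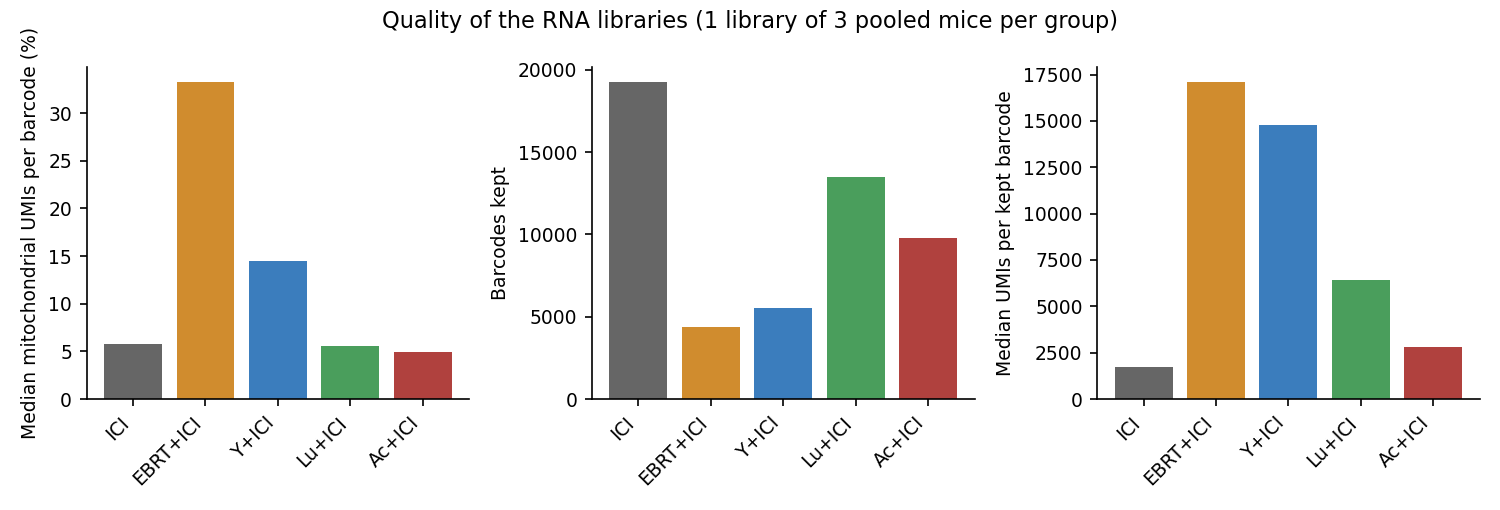
Bars show the median percentage of mitochondrial UMIs per deposited barcode, the number of barcodes kept and the median UMIs per kept barcode in the 1 RNA library of each group. The EBRT library has the highest mitochondrial median, 33.2%, and the fewest kept barcodes, 4380.

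Melanoma cells, although CD45+ cells were loaded, were the most abundant named class and made up 19.2% of the kept barcodes in ICI, 68.4% in EBRT, 58.4% in 90Y, 44.5% in 177Lu and 29.6% in 225Ac. CD8 T cells numbered 169, 63, 168, 244 and 129, and regulatory T cells (Treg) 238, 115, 194, 560 and 259. Macrophages numbered 1139, 134, 421, 685 and 649. Cluster 12, led by Mmp12, Ccl6 and Arg1, held 48.0%, 64.2%, 61.5%, 54.6% and 64.9% of them. Cluster 14, led by Ccl7, Ccl12, Ccl2 and C1q genes, held the rest. Levels of these genes may partly reflect this mix, not split in EBRT (86 and 48 cells). The macrophage share of kept barcodes was 5.92% (exact 95% interval 5.59 to 6.26) in ICI, 3.06% (2.57 to 3.61) in EBRT, 7.59% (6.91 to 8.32) in 90Y, 5.07% (4.70 to 5.45) in 177Lu and 6.63% (6.15 to 7.15) in 225Ac. Its ratio to ICI had no settled direction: 0.517, 1.28, 0.856 and 1.12 became 1.51, 3.75, 2.54 and 2.69 with equal doublet removal, which took the largest percentage from ICI. They became 0.0808, 0.212, 0.401 and 0.440 with a gate on C1q genes, 0.225, 0.585, 0.483 and 0.667 without barcodes low in nuclear RNA, and 0.118, 0.450, 0.533 and 0.886 with a stricter cell filter. The EBRT ratio was 0.865 with the wider mitochondrial limit, and the EBRT and 225Ac ratios were 0.795 and 0.634 among leukocytes. On cells thinned to 1000 UMIs, for which 4967, 28, 114, 1815 and 1732 shallower cells were left out, the C1q gate took 48.3%, 3.91%, 10.2%, 19.4% and 21.3% of cells, against 2.74%, 0.670%, 0.497%, 0.904% and 0.837% of the melanoma class, which should lack these genes.

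**Figure D2:**
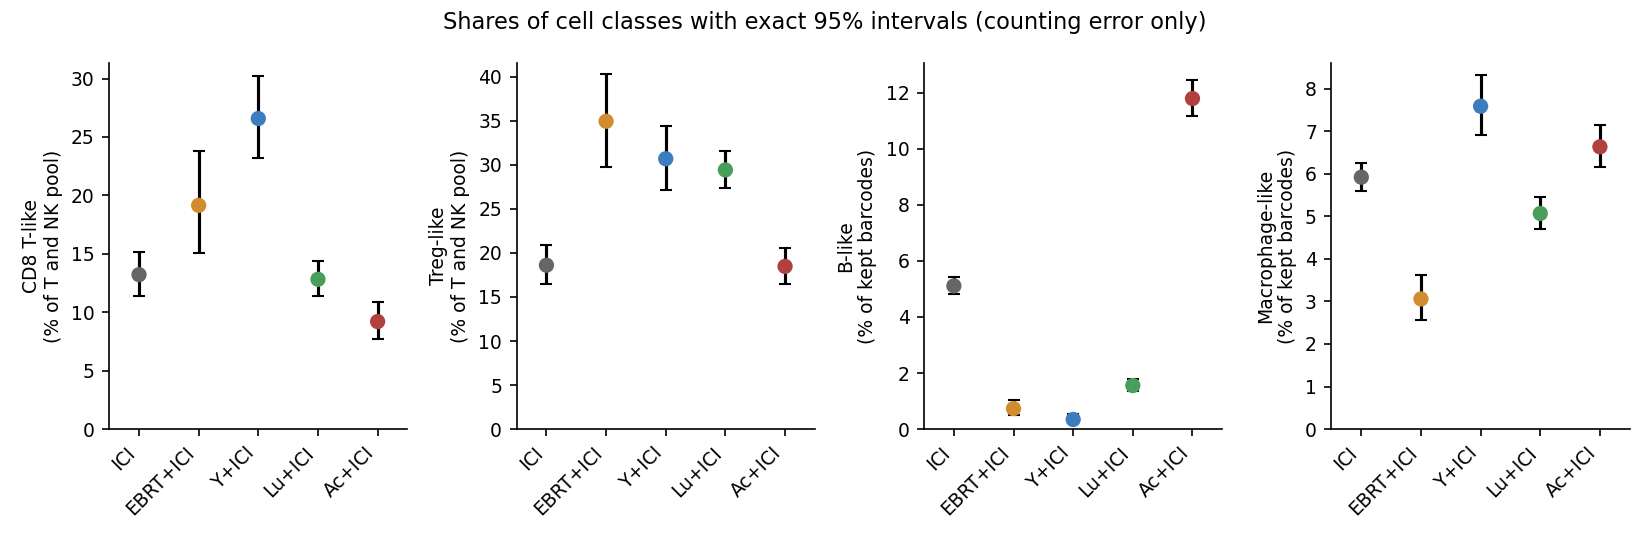
Points show the share of each class in each group as a percentage of the T and NK pool or of kept barcodes, and bars show exact 95% intervals for counting error. Treg shares sit between 29.4% and 35.0% in EBRT, 90Y and 177Lu, against 18.6% in ICI and 18.5% in 225Ac.

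The comparison of EBRT plus ICI with ICI alone asks what external radiation at this dose added to checkpoint blockade. Treg took a larger share of the T and NK pool after EBRT, 35.0% (29.8 to 40.4) against 18.6% (16.5 to 20.9), a ratio of 1.88 (1.49 to 2.36). The Treg class left out an unnamed sub-cluster that carried Foxp3 and Ctla4 together with macrophage transcripts. It held 5.94% of the pool in ICI and 2.13% in EBRT. Counting it as Treg was not tried and would lower the ratio. Before the pool was clustered again, the Treg cluster held 328 of 1279 pool cells in ICI and 96 of 329 in EBRT, a smaller difference. In macrophages, 4 of 9 MHC class II and 5 of 15 repair genes were higher than in ICI, while 10 of 16 chemokine and 11 of 20 cell cycle genes were lower. The MHC class II and cell cycle medians changed sign with equal doublet removal. Retnla (ENSMUSG00000061100), a secreted product of alternatively activated macrophages, reached 1189 CPM against 11.2 CPM, a ratio of 106 (86.0 to 131). Type I interferon genes had medians below 0 in Treg and macrophages, that of macrophages with a change of sign under equal doublet removal. The CD8 T cell share was 19.1% (15.0 to 23.8) against 13.2% (11.4 to 15.2), and its ratio of 1.45 (1.07 to 1.95) stayed under the size rule of 1.5 times and was 0.804 with a marker gate within the T and NK pool. Of cells with at least 1000 UMIs that gate took 2.33% in ICI and 1.63% in EBRT, and 0% of the melanoma class in both. B cells fell from 5.11% (4.80 to 5.43) of kept barcodes to 0.731% (0.5002 to 1.03), a ratio of 0.143 (0.0972 to 0.203). This direction was lost when cells of up to 25% mitochondrial UMIs were kept, which gave 1.17, and the ratio was 0.0303 with the stricter filter, 0.0621 without barcodes low in nuclear RNA and 0.220 among leukocytes. Between EBRT and ICI the median log2 ratio over all genes was -0.20 in macrophages and -0.12 in melanoma cells.

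In Treg of the EBRT group, the proliferation list had a median log2 ratio of 0.20, above 92.2% of random lists matched for level, with 5 of 20 measured members higher and 2 lower by the size rule. Pcna, the sliding clamp of DNA replication, was 2.54 times (1.83 to 3.54) and Top2a 1.52 times (1.15 to 2.02) its ICI level, whereas Ccnb1, a mitotic cyclin, was at 0.394 (0.146 to 0.919). This median was -0.01 with members of at least 100 UMIs, 1.54 with equal doublet removal and -0.93 with the wider mitochondrial limit. The type I interferon list had a median of -0.25, above 13.4% of random lists, and 1 of 11 members was higher. Immediate early and stress genes, which also respond to tissue dissociation, had a median of -0.68, below all matched lists, and 7 of 13 were lower, including Fos at 0.464 (0.291 to 0.718) and Jun at 0.312 (0.174 to 0.528). By the named-gene rule, Sipa1l1 was 3.78 times (2.75 to 5.25), Kdm2b 3.05 times (2.45 to 3.81), Dgat1 3.05 times (2.49 to 3.74) and the genome organiser Satb1 3.02 times (2.15 to 4.29) its ICI level. With each cell weighted equally, the log2 ratio of Satb1 was 1.01 against 1.60. Ccr8, a chemokine receptor of tumour Treg, fell to 0.362 (0.283 to 0.459), with Coro1b at 0.321 (0.198 to 0.5005), Pkp3 at 0.343 (0.234 to 0.491) and Smpdl3a at 0.347 (0.213 to 0.542). On data simulated at the depth of this Treg comparison, the rule recovered 32.8% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold.

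Macrophages of the EBRT group had an MHC class II median of 0.51, above 99.95% of random lists, with 4 of 9 members higher, among them H2-Ab1 at 1.76 times (1.70 to 1.82) and its regulator Ciita at 1.79 times (1.18 to 2.62). The interferon gamma list had a median of 0.38 with 4 of 15 members higher and 1 lower, and Irf1, an interferon-induced transcription factor, was at 1.84 times (1.43 to 2.33). With members of at least 100 UMIs this median was -0.52. The type I interferon list split, with 4 of 26 members higher, such as Oas3 at 2.45 times (1.64 to 3.57), and 9 lower, such as Isg15 (ENSMUSG00000035692), a ubiquitin-like interferon product, at 0.529 (0.446 to 0.622) and Ifit3 at 0.486 (0.328 to 0.696). Its median was -0.19, above 11.3% of random lists, and -0.79 with members of at least 100 UMIs. Chemokine genes had a median of -0.98, below all matched lists, with 10 of 16 lower and 2 higher. The monocyte attractants Ccl2 and Ccl12 fell to 0.455 (0.422 to 0.491) and 0.302 (0.277 to 0.329), and Ccl6 rose 3.80 times (3.49 to 4.14). The immunosuppressive and repair list had a median of 0.40, above 99.76% of random lists, with 5 of 15 higher and 1 lower. Among these, Arg1 was at 2.04 times (1.73 to 2.40) and Mmp12 at 2.94 times (2.70 to 3.19). The inflammatory macrophage list had a median of -0.44 with 1 of 12 higher and 5 lower, including Tnf at 0.653 (0.541 to 0.781), and this median was 0.05 with the wider mitochondrial limit.

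Proliferation genes of these macrophages had a median of -0.60, below all matched lists, with 11 of 20 lower, such as Birc5 at 0.464 (0.331 to 0.634) and Mki67 at 0.655 (0.491 to 0.858). Hypoxia and glycolysis genes had a median of -0.29 with 5 of 17 lower and 1 higher, and the glycolytic enzymes Ldha and Aldoa were at 0.613 (0.568 to 0.660) and 0.510 (0.476 to 0.547). Immediate early and stress genes had a median of -0.50 with 6 of 16 lower and 1 higher, and Fos was at 0.591 (0.549 to 0.635). Erythroid transcripts, a sign of blood in the sample, had a median of -4.65 with 4 of 5 lower, and Hbb-bs had 1 UMI against 565, a ratio of 0.0202 (0.00051 to 0.113). The erythroid median was -4.07 with all members detected and -5.54 with the wider mitochondrial limit. Melanoma transcripts had a median of -0.99 over 3 members, of which 1 was higher and 1 lower, against -0.11 with all members detected and -1.64 with the wider mitochondrial limit. By the named-gene rule the monocyte marker Ly6c2 was 8.04 times (7.08 to 9.12), the matrix protein gene Thbs1 5.71 times (4.93 to 6.60) and Adgre5 5.12 times (4.12 to 6.33) its ICI level. Lower genes were Cxcl14, with 2 UMIs against 499 and a ratio of 0.0457 (0.00552 to 0.166), Fcrls at 0.232 (0.195 to 0.274), Olfml3 at 0.274 (0.195 to 0.375) and Ang at 0.276 (0.146 to 0.475). With cells weighted equally the log2 ratio of Ang was -1.28 against -1.86, and that of Retnla 5.67 against 6.72. Equal doublet removal turned the MHC class II median to -0.09, the type I interferon median to 0.15 and the proliferation median to 0.82.

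The comparison of 90Y-NM600 plus ICI with ICI alone asks what this beta emitter added. CD8 T cells made up 26.6% (23.2 to 30.2) of the T and NK pool against 13.2%, a ratio of 2.01 (1.62 to 2.51), and Treg 30.7% (27.1 to 34.5) against 18.6%, a ratio of 1.65 (1.36 to 2.00). Ccl3 was at 104 CPM against 820 CPM in the CD8 T cells. There 6 of 13 effector, 3 of 5 residency and 5 of 11 glycolysis genes were lower. So were 7 of 19 cell cycle genes, with a median that changed sign under equal doublet removal. In macrophages 13 of 20 cell cycle genes, whose median also changed sign there, and 9 of 16 chemokine genes were lower than in ICI, and B cells were few, at 0.343% (0.206 to 0.534) of kept barcodes. Their ratio to ICI was 0.0670 (0.0402 to 0.105), and it was 0.0317 with the stricter filter, 0.0306 without barcodes low in nuclear RNA and 0.130 with the wider mitochondrial limit. The CD8 T ratio was 1.43 when 2 unnamed sub-clusters were counted as CD8 T and 0.986 with the marker gate in the pool, which took 3.00% of 90Y cells with at least 1000 UMIs and 0% of their melanoma class. The Treg ratio was 1.46 with equal doublet removal, 1.40 at the lower clustering resolution and 1.49 without the Lef1-led sub-cluster, each under the size rule.

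In CD8 T cells of the 90Y group, cytotoxic effector genes had a median log2 ratio of -0.33, above 6.09% of random lists, with 6 of 13 lower and 1 higher. The killing protease Gzmb was at 0.641 (0.537 to 0.762), the cytokine Ifng at 0.593 (0.440 to 0.794), Ccl3 at 0.127 (0.0949 to 0.166) and Ccl4 at 0.281 (0.250 to 0.316), while Gzma was at 3.26 times (1.40 to 8.47). Residency genes had a median of -0.87, above 0.09% of random lists, with 3 of 5 lower, among them the tissue-homing receptor Cxcr6 at 0.502 (0.414 to 0.607) and Cd69 at 0.546 (0.339 to 0.860), and a median of -0.36 with the 2 unnamed sub-clusters counted as CD8 T. Stem-like and memory genes had a median of 0.64, above 96.7% of random lists, with 2 of 5 higher, Lef1 at 2.37 times (1.102 to 5.42) and Bach2 at 3.02 times (1.77 to 5.36). That median was -0.22 with these sub-clusters counted. Inhibitory receptor genes had a median of -0.22 with 1 of 14 lower, Havcr2, the receptor TIM-3, at 0.555 (0.363 to 0.834). Proliferation genes had a median of -0.62 with 7 of 19 lower, Mki67 at 0.408 (0.283 to 0.578), and a median of 0.21 with equal doublet removal. Hypoxia and glycolysis genes had a median of -0.76, below all matched lists, with 5 of 11 lower, Ldha at 0.567 (0.495 to 0.648). The type I interferon median was -0.16 with 1 of 10 higher, Isg15 at 2.01 times (1.31 to 3.12). By the named-gene rule Lncpint was at 4.05 times (2.87 to 5.84), Hivep2 at 3.36 times (2.41 to 4.76), the repressor Zeb1 at 3.18 times (2.35 to 4.36) and Kdm2b at 2.74 times (2.03 to 3.74), and lower genes were Ccl3, Ccl4, Hist1h1e at 0.275 (0.201 to 0.371) and Dusp1 at 0.339 (0.282 to 0.406). The log2 ratio of Hivep2 was 1.00 with cells weighted equally, against 1.75. On data simulated at the depth of this comparison, 43.3% of 67 genes changed 1.5-fold, 74.6% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered.

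In Treg of the 90Y group, proliferation genes had a median of 0.27, above 97.7% of random lists, with 6 of 20 higher and 1 lower. The replication genes Mcm5 and Pcna were at 2.49 times (1.60 to 3.97) and 2.25 times (1.65 to 3.09), and Cenpf, which acts in mitosis, was at 0.481 (0.274 to 0.819). The median was 1.71 with equal doublet removal and -0.27 with the wider mitochondrial limit. Type I interferon genes had a median of -0.16 with 3 of 13 lower, such as Irf7 (ENSMUSG00000025498), which drives interferon production, at 0.508 (0.273 to 0.909). Immediate early and stress genes had a median of -0.44 with 5 of 13 lower, Fos at 0.463 (0.312 to 0.677) and Jun at 0.371 (0.237 to 0.566). The named-gene rule gave Antxr2 at 3.43 times (2.32 to 5.17), Sipa1l1 at 2.76 times (2.02 to 3.82), Ell2 at 2.69 times (1.87 to 3.92) and Lyn at 2.67 times (1.85 to 3.92). Lower were Zfp36l1 at 0.393 (0.343 to 0.450), the tetraspanin Cd81 at 0.440 (0.348 to 0.553), Dusp1 at 0.466 (0.410 to 0.530) and the stress-induced Ddit4 at 0.471 (0.385 to 0.575).

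Macrophages of the 90Y group had a proliferation median of -0.84, below all matched lists, with 13 of 20 lower, Birc5 at 0.436 (0.358 to 0.527) and Mki67 at 0.555 (0.464 to 0.660). Chemokine genes had a median of -0.79 with 9 of 16 lower and 2 higher, Ccl2 at 0.428 (0.409 to 0.448), Ccl12 at 0.358 (0.342 to 0.375) and Ccl6 at 2.09 times (1.95 to 2.24). Type I interferon genes had a median of -0.16 with 5 of 27 higher, such as Oas3 at 1.99 times (1.51 to 2.60), and 5 lower, such as Isg15 at 0.657 (0.601 to 0.717) and Ifit3 at 0.473 (0.377 to 0.587). MHC class II genes had a median of 0.28, above 99.5% of random lists, yet no member of 9 was higher by the size rule and 2 were lower. H2-Aa was at 1.24 times (1.21 to 1.27), and H2-Oa had 3 UMIs against 47, a ratio of 0.233 (0.0465 to 0.725). Erythroid transcripts had a median of 1.53 with 4 of 4 higher, Hbb-bs at 2.43 times (2.12 to 2.77). Melanoma transcripts had a median of -0.63 over 3 members, with Mitf at 1.54 times (1.33 to 1.77) and 1 member lower. The named-gene rule gave Retnla at 14.1 times (11.3 to 17.8), Mmp19 at 8.27 times (6.14 to 11.3), Inhba at 6.33 times (4.69 to 8.61) and Thbs1 at 5.83 times (5.24 to 6.49). Lower were the histone genes Hist1h1b at 0.278 (0.206 to 0.368), Hist1h2ae at 0.306 (0.219 to 0.418) and Hist1h1e at 0.318 (0.245 to 0.406), and Cbr2 at 0.312 (0.249 to 0.386). With cells weighted equally the log2 ratio of Retnla was 3.12 against 3.82. Equal doublet removal turned the medians of proliferation to 0.95, type I interferon to 0.19 and MHC class II to -0.36, and moved the erythroid median to 6.10, while the MHC class II median was -0.09 and the erythroid median 3.27 in cluster 12, and the erythroid median -4.02 in cluster 14.

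The comparison of 177Lu-NM600 plus ICI with ICI alone asks the same of the other beta emitter. Treg made up 29.4% (27.4 to 31.5) of the T and NK pool against 18.6%, a ratio of 1.58 (1.36 to 1.85), and CD8 T cells 12.8% (11.4 to 14.4) against 13.2%, a ratio of 0.970 (0.794 to 1.19). B cells made up 1.55% (1.35 to 1.78) of kept barcodes, a ratio of 0.304 (0.261 to 0.353). In macrophages Retnla and 4 of 9 MHC class II genes were higher and 14 of 20 cell cycle genes lower than in ICI. Both list medians changed sign with equal doublet removal. Gzma, a granule protease, was at 74.5 CPM against 12.1 CPM in CD8 T cells, a ratio of 6.16 (2.89 to 15.1). The Treg ratio went under the size rule with equal doublet removal (1.49), at the lower and higher clustering resolutions (1.46 and 1.30) and without the Lef1-led sub-cluster (1.45). The CD8 T ratio was 1.02 at the higher resolution, and the B ratio was 0.160 with the stricter filter and 0.172 without barcodes low in nuclear RNA. The median over all genes was -0.17 in B cells between 177Lu and ICI.

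In the 177Lu group, type I interferon genes had a median of 0.34 in CD8 T cells, above 98.7% of random lists, although none of 10 members passed the size rule and the median was 0.00 with the 2 unnamed sub-clusters counted as CD8 T. In Treg, macrophages and B cells their medians took either sign under other settings: -0.01 in Treg with none of 15 past the rule (up to 0.21 with members of at least 100 UMIs), 0.05 in macrophages (-0.15 in cluster 12) and -0.22 in B cells with none of 13 past the rule (0.21 with all members detected). In macrophages 1 of 27 was higher, the RNA sensor gene Oas2 at 1.80 times (1.35 to 2.39), and 1 lower, Ifit2 at 0.635 (0.550 to 0.730). The cytotoxic effector median in CD8 T cells was 0.05 with 1 of 13 members higher, Gzma, and -0.07 with equal doublet removal, and Gzmb was at 0.780 (0.666 to 0.913). By the named-gene rule CD8 T cells had Il31ra at 2.26 times (1.92 to 2.68), the inositol phosphatase gene Inpp5d at 2.11 times (1.58 to 2.85) and Pik3cd at 2.05 times (1.51 to 2.81). Il31ra was also a leading gene of a T and NK sub-cluster low in nuclear RNA and of an unnamed cluster mixed with melanoma transcripts. Arrb2 was at 0.493 (0.357 to 0.675), Ube2n at 0.504 (0.356 to 0.707), the glycolytic Pgam1 at 0.529 (0.432 to 0.646) and Hnrnpdl at 0.554 (0.407 to 0.7503).

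In Treg of the 177Lu group, proliferation genes had a median of -0.23 with 1 of 20 higher, Pcna at 1.502 times (1.12 to 2.03), and 1 lower, Ccnb1 at 0.523 (0.304 to 0.904). This median was 0.03 with members of at least 100 UMIs, 0.06 with cells weighted equally and 1.11 with equal doublet removal. Immediate early and stress genes had a median of -0.41, below all matched lists, with 5 of 15 lower, including Junb at 0.604 (0.571 to 0.639), Nr4a1, induced by TCR signalling, at 0.508 (0.422 to 0.611) and the chaperone gene Hspa1a at 0.276 (0.124 to 0.582). Under the named-gene rule, Setbp1 was at 3.04 times (1.86 to 5.23), Angptl2 at 2.24 times (1.45 to 3.57), the suppressive cytokine Il10 at 2.22 times (1.44 to 3.54) and Adcy7 at 1.95 times (1.27 to 3.10). Lower, beside Nr4a1 and Junb, were Ncf4 at 0.589 (0.453 to 0.767) and the histone variant gene H2afx at 0.611 (0.471 to 0.793).

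In macrophages of the 177Lu group, MHC class II genes had a median of 0.55, above all matched lists, with 4 of 9 higher and 1 lower, H2-Ab1 at 1.59 times (1.55 to 1.62) and Ciita at 1.83 times (1.47 to 2.27). Proliferation genes had a median of -0.69 with 14 of 20 lower, Birc5 at 0.511 (0.439 to 0.593). Chemokine genes had a median of -0.27 with 7 of 17 lower, such as Ccl2 at 0.470 (0.453 to 0.487) and Ccl12 at 0.468 (0.452 to 0.484), and 5 higher, such as the T cell attractant Ccl5 at 1.57 times (1.47 to 1.68) and the eosinophil attractant Ccl24 at 8.64 times (4.03 to 20.6). Immediate early and stress genes had a median of -0.45 with 5 of 16 lower, Fos at 0.609 (0.588 to 0.631) and Egr1 at 0.463 (0.423 to 0.505), and 2 higher, such as Hspa1a at 1.77 times (1.64 to 1.91). Erythroid transcripts had a median of 2.34 with 5 of 5 higher, Hbb-bs at 4.64 times (4.19 to 5.15), and melanoma transcripts a median of 0.74 with 2 of 3 higher. By the named-gene rule Retnla was at 46.4 times (38.0 to 57.2), Hspb1 at 2.86 times (2.51 to 3.27), Gstp1 at 2.29 times (1.93 to 2.73) and the complement gene C3 at 1.89 times (1.58 to 2.26). Hist1h1b was at 0.380 (0.308 to 0.466), Tnfsf9 at 0.384 (0.339 to 0.435), Tnf at 0.402 (0.359 to 0.449) and Cbr2 at 0.450 (0.385 to 0.524). With cells weighted equally the log2 ratios of Retnla and Hspb1 were 4.17 and 0.93, against 5.54 and 1.52. Equal doublet removal gave medians of -0.03 for MHC class II, 1.14 for proliferation and 6.91 for erythroid transcripts, which had 3.49 in cluster 12.

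The comparison of 225Ac-NM600 plus ICI with ICI alone asks what the alpha emitter added. Type I interferon response genes were higher in CD8 T cells, Treg, macrophages and B cells of the 225Ac group, each list lying above all 10000 matched random lists. Isg15 rose to 364 CPM from 101 CPM in Treg, a ratio of 3.61 (2.81 to 4.69), and to 864 CPM from 365 CPM in macrophages, a ratio of 2.37 (2.26 to 2.48). In macrophages 13 of 18 interferon gamma, 6 of 13 MHC class I and 4 of 9 checkpoint ligand genes were also higher, and 18 of 20 cell cycle genes were lower, a difference that equal doublet removal took to a median of -0.04. B cells made up 11.8% (11.2 to 12.5) of kept barcodes, 2.31 times (2.12 to 2.52) the ICI share, and 1.37 times without barcodes low in nuclear RNA and 1.31 times among leukocytes, both under the size rule. Treg made up 18.5% (16.5 to 20.6) of the T and NK pool, a ratio of 0.993 (0.829 to 1.19) that reached 1.22 without the Lef1-led sub-cluster. CD8 T cells made up 9.20% (7.74 to 10.8), a ratio of 0.696 (0.549 to 0.881) that stayed inside the size rule and was 1.13 when EBRT and 90Y were left out of the clustering. The Lef1-led sub-cluster, also marked by the naive T cell genes Ccr7 and Tcf7, held 27.5% of the pool in 225Ac, 11.1% in ICI, 8.81% in EBRT, 1.42% in 90Y and 3.21% in 177Lu. It also carried Cd8a and Cd8b1 but was left unnamed, so the CD8 T shares leave out its 385 cells in 225Ac and 142 in ICI.

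**Figure D3:**
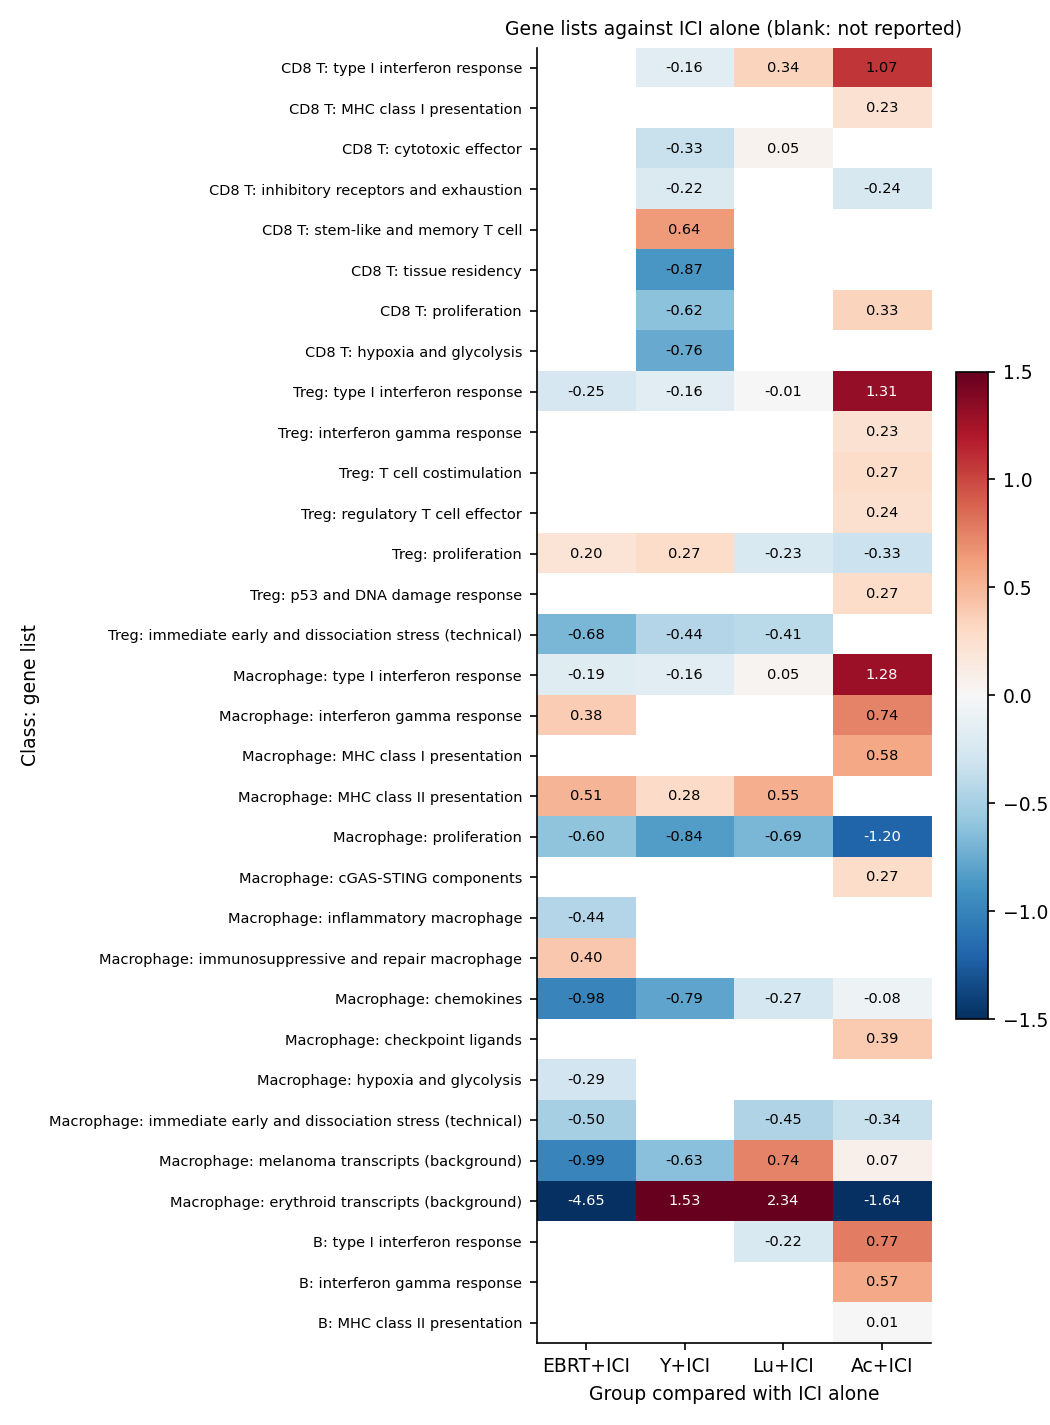
Cells of the grid give the median log2 ratio of each reported gene list in CD8 T cells, Treg, macrophages or B cells of 1 radiation group against ICI alone, with colour limited at 1.5 on either side. In these classes, type I interferon medians in the 225Ac column run from 0.77 in B cells to 1.31 in Treg, and those of the other columns from -0.25 to 0.34.

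In CD8 T cells of the 225Ac group, type I interferon genes had a median of 1.07 with 8 of 11 higher, such as Isg15 at 2.66 times (1.74 to 4.13) and Irf7 at 2.21 times (1.37 to 3.61). MHC class I genes had a median of 0.23, above 99.7% of random lists, with 1 of 13 higher, the peptide transporter gene Tap1 at 1.51 times (1.15 to 1.98), and a median of 0.08 when EBRT and 90Y were left out of the clustering. Inhibitory receptor and exhaustion genes had a median of -0.24, above 1.25% of random lists, with 2 of 13 lower, Nr4a2 at 0.633 (0.529 to 0.755) and Eomes at 0.612 (0.396 to 0.927), and a median of -0.66 in that clustering. Proliferation genes had a median of 0.33 with 1 of 19 higher, Birc5 at 1.84 times (1.31 to 2.58), and a median of -0.34 in that clustering. By the named-gene rule Ifi27l2a was at 3.36 times (3.04 to 3.71), Ly6c2 at 3.20 times (2.46 to 4.19), Ly6a at 2.99 times (2.56 to 3.49) and Bst2, which tethers budding virus, at 2.68 times (2.04 to 3.54). Eif4b was at 0.380 (0.242 to 0.5795), Ccl3 at 0.389 (0.321 to 0.470), Tkt at 0.539 (0.375 to 0.763) and Cct7 at 0.555 (0.399 to 0.763).

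Treg of the 225Ac group had a type I interferon median of 1.31 with 16 of 18 members higher, such as Irf7 at 2.86 times (1.96 to 4.23) and the translation inhibitor gene Ifit1 at 3.45 times (1.52 to 8.78). Interferon gamma genes had a median of 0.23 with 3 of 13 higher. The p53 and DNA damage list had a median of 0.27, above 96.6% of random lists, with 2 of 12 higher, the cell cycle inhibitor Cdkn1a at 2.15 times (1.57 to 2.97) and Mdm2, which limits p53, at 1.82 times (1.22 to 2.74). Treg effector genes had a median of 0.24, above 99.7% of random lists, with 3 of 15 higher: Il10 at 2.28 times (1.41 to 3.77), Areg, a repair growth factor, at 1.74 times (1.53 to 1.97) and Gzmb at 2.62 times (2.15 to 3.20). Costimulation genes had a median of 0.27, and none of 8 passed the size rule. Proliferation genes had a median of -0.33 with 6 of 20 lower, Cdk1 at 0.404 (0.216 to 0.723), and a median of 0.41 with equal doublet removal. The named-gene rule added Lgals3bp at 3.58 times (2.5003 to 5.22) and Rnf213 at 3.42 times (2.52 to 4.71) to Isg15 and Irf7, and on the lower side Nr4a1 at 0.493 (0.391 to 0.620), Nfkbid at 0.528 (0.382 to 0.723), Rpn2 at 0.567 (0.413 to 0.772) and Tcp1 at 0.586 (0.422 to 0.809). In B cells the type I interferon median was 0.77 with 13 of 22 higher, Ifit3 at 2.30 times (1.36 to 4.03) and Oas2 at 3.19 times (1.33 to 8.77). Interferon gamma genes of B cells had a median of 0.57 with 3 of 13 higher, among them Irf1 at 1.60 times (1.27 to 2.03) and Socs1 at 2.20 times (1.35 to 3.66), and 1 lower, Cxcl9 at 0.343 (0.197 to 0.574). Their MHC class II median was 0.01 with none of 9 past the rule, and -0.02 with TMM factors.

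Macrophages of the 225Ac group had a type I interferon median of 1.28 with 23 of 27 higher, such as Ifit3 at 2.32 times (2.09 to 2.57) and Irf7 at 2.68 times (2.49 to 2.89). Interferon gamma genes had a median of 0.74, above all matched lists, with 13 of 18 higher, such as the guanylate-binding protein gene Gbp5 at 2.10 times (1.69 to 2.62), and 1 lower, the T cell attractant Cxcl9 at 0.417 (0.370 to 0.470). MHC class I genes had a median of 0.58 with 6 of 13 higher, H2-K1 at 1.66 times (1.62 to 1.71), Tap1 at 1.63 times (1.47 to 1.82) and the transactivator Nlrc5 at 1.84 times (1.53 to 2.21). Checkpoint ligand genes had a median of 0.39 with 4 of 9 higher, including Cd274, which encodes the PD-L1 targeted by the treatment, at 1.57 times (1.42 to 1.75), Pdcd1lg2 at 3.22 times (1.63 to 6.53) and Cd80, a ligand of CTLA4 and CD28, at 2.99 times (2.15 to 4.18). The cGAS-STING list had a median of 0.27 with 2 of 9 higher and 1 lower, and -0.01 with members of at least 100 UMIs. The DNA sensor gene Ifi204 was at 2.59 times (2.34 to 2.86), and Ifnb1, which encodes interferon beta, was at 8.995 CPM against 37.6 CPM, a ratio of 0.239 (0.165 to 0.337). Chemokine genes had a median of -0.08 with 6 of 16 lower and 2 higher, Ccl3 at 0.452 (0.428 to 0.478) and Ccl12 at 0.594 (0.577 to 0.612), and a median of 0.00 with equal doublet removal. On data simulated at this depth, 37.3% of 67 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered.

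Proliferation genes of these macrophages had a median of -1.20, below all matched lists, with 18 of 20 lower, Mki67 at 0.389 (0.328 to 0.458) and Top2a at 0.441 (0.366 to 0.528), and a median of -0.04 with equal doublet removal. Immediate early and stress genes had a median of -0.34 with 5 of 16 lower, Fos at 0.666 (0.644 to 0.689). Erythroid transcripts had a median of -1.64 with 5 of 5 lower, which became 3.91 with equal doublet removal, -0.68 with cells weighted equally, 0.13 in cluster 12 and -5.01 in cluster 14. Melanoma transcripts had a median of 0.07 over 3 members, with Mitf at 1.54 times (1.37 to 1.74) and 1 member lower, and -0.09 in cluster 12. The named-gene rule gave the acute phase gene Saa3 at 10.2 times (7.54 to 14.2), Ly6c2 at 10.1 times (9.22 to 11.02), Npy at 9.35 times (6.90 to 12.9) and Slfn4 at 7.202 times (6.20 to 8.39). With cells weighted equally their log2 ratios were 4.06 for Saa3 against 3.36, 2.28 for Npy against 3.23 and 2.13 for Slfn4 against 2.85. Lower were Cxcl14 at 0.229 (0.168 to 0.306), Egr1 at 0.324 (0.293 to 0.357), Tnf at 0.334 (0.296 to 0.375) and Cdca8 at 0.360 (0.280 to 0.458).

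Each NM600 form was compared with EBRT to ask whether the same labelled dose from a radiopharmaceutical gave another immune profile. The 225Ac group had higher type I interferon genes than EBRT, with medians of 1.60 in Treg (16 of 18 higher) and 1.31 in macrophages (24 of 27 higher), both above all matched lists. Irf7 was at 5.25 times (2.94 to 10.2) in Treg, and Isg15 at 4.48 times (3.80 to 5.30) in macrophages. The 90Y and 177Lu groups differed from EBRT less in these genes and had medians below 0 for the repair list in macrophages. Treg shares were 0.878 (0.694 to 1.12) times that of EBRT in 90Y, 0.842 (0.688 to 1.04) times in 177Lu and 0.529 (0.423 to 0.664) times in 225Ac, and the 90Y value was 1.01 with the wider mitochondrial limit. CD8 T shares were 1.39 (1.03 to 1.89), 0.670 (0.506 to 0.898) and 0.481 (0.353 to 0.660) times that of EBRT, where the first was 0.954 with the stricter filter and the third 1.07 with the marker gate. With 63 CD8 T cells in EBRT, gene levels of that class were not compared. Over all genes, the median log2 ratio against EBRT was 0.12 in Treg and 0.12 in macrophages of 177Lu, and 0.12 in macrophages of 225Ac.

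Treg of the 90Y group had a type I interferon median of 0.02 against EBRT with none of 9 past the rule, and of -0.11 with the wider mitochondrial limit. Their proliferation median was 0.14, with 3 members higher, such as Ccnb1 at 2.41 times (1.01 to 6.59), and 2 lower, such as Cenpf at 0.295 (0.168 to 0.502), and it was -0.26 with cells weighted equally. Their stress median was 0.17 with 1 of 11 higher, Dnajb1 at 1.75 times (1.15 to 2.72). In their macrophages the type I interferon median was 0.06 with 2 of 25 higher, such as Ifit1 at 1.65 times (1.03 to 2.77), and the repair list had a median of -0.47 with 7 of 15 lower, such as Mmp12 at 0.635 (0.581 to 0.695). The named-gene rule gave Retnla at 0.134 (0.118 to 0.151), Fat3 at 0.353 (0.270 to 0.462) and Ccl8 at 0.462 (0.417 to 0.512), and the heat shock genes Hspa1a at 6.21 times (4.71 to 8.34), Hsph1 at 4.84 times (3.04 to 8.16) and Hspa1b at 4.04 times (3.02 to 5.52).

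Treg of the 177Lu group had a type I interferon median of 0.46 against EBRT with 2 of 17 higher, Ifih1 at 2.85 times (1.14 to 9.19) and Ifit3, which had 1 UMI in EBRT, at 6.82 times (1.102 to 281). With cells weighted equally the log2 ratio of Ifit3 was 3.99 against 2.77. Proliferation genes had a median of -0.35 with 4 members lower, Pcna at 0.591 (0.461 to 0.763), and 0.60 with the wider mitochondrial limit. Stress genes had a median of 0.44 with 3 of 12 higher, Jun at 3.32 times (2.02 to 5.82) and Dusp1 at 1.95 times (1.68 to 2.27). In macrophages the type I interferon median was 0.08 with 6 of 26 higher, such as Isg15 at 1.65 times (1.39 to 1.97), and 1 lower, Oas3 at 0.520 (0.345 to 0.799). Repair genes had a median of -0.45 with 5 of 14 lower, such as Retnla at 0.439 (0.406 to 0.475), and 1 higher, Ccl8 at 1.51 times (1.39 to 1.65). Chemokine genes had a median of 0.54 with 8 of 16 higher, such as Ccl12 at 1.55 times (1.41 to 1.69), and 3 lower, such as Ccl6 at 0.397 (0.362 to 0.436). The named-gene rule gave Thbs1 at 0.280 (0.239 to 0.328), Rgcc at 0.302 (0.236 to 0.387), Kdm6b at 0.330 (0.270 to 0.403), Hspa1a at 4.66 times (3.54 to 6.26) and Hsph1 at 4.28 times (2.70 to 7.19). Hspb1 had 496 UMIs against 0, at least 5.14 on the log2 scale with a floor of 3 UMIs in the EBRT class sum. With doublets kept, the log2 ratio of Hsph1 was 1.60 against 2.28 for 90Y and 1.39 against 2.10 for 177Lu.

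Treg of the 225Ac group had Isg15 at 2.68 times (2.05 to 3.56) its EBRT level. Proliferation genes had a median of -0.57 with 7 of 19 lower, Top2a at 0.632 (0.474 to 0.843), and of -1.21 with equal doublet removal and 0.44 with the wider mitochondrial limit. The p53 and DNA damage list had a median of 0.63 with 6 of 12 higher, Cdkn1a at 1.58 times (1.13 to 2.23) and Ddit4 at 2.82 times (2.20 to 3.65). Stress genes had a median of 0.56 with 6 of 12 higher, Fos at 2.02 times (1.30 to 3.23). In macrophages Irf7 was at 3.84 times (3.05 to 4.90), and the interferon gamma list had a median of 0.29 with 5 of 17 higher, Gbp6 at 3.25 times (1.44 to 9.06) and Cxcl10 at 2.17 times (1.80 to 2.64), and 1 lower, Cxcl9 at 0.599 (0.480 to 0.753). The named-gene rule gave Retnla at 0.00841 (0.00597 to 0.0115), Egr1 at 0.270 (0.234 to 0.312), Kdm6b at 0.327 (0.269 to 0.398), Ifi206 at 6.00 times (3.22 to 12.6), Slfn4 at 5.76 times (3.87 to 8.96) and Hspb1, with 465 UMIs against 0, at least 4.93 on the log2 scale.

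The NM600 forms were compared with each other because the title of the series asks whether immunity varies with the radioisotope. Type I interferon genes were higher in 225Ac than in 90Y and 177Lu in CD8 T cells, Treg and macrophages, with each list above all matched lists. Against 90Y the medians were 0.84 in CD8 T cells (7 of 11 higher), 1.55 in Treg (17 of 18) and 1.27 in macrophages (25 of 27). Against 177Lu they were 0.72 (6 of 11), 1.23 (16 of 18) and 1.25 (26 of 27). Isg15 in macrophages was at 3.602 times (3.30 to 3.94) its 90Y level and 2.71 times (2.54 to 2.90) its 177Lu level, and in Treg at 3.21 times (2.499 to 4.15) and 3.64 times (2.98 to 4.45). Treg shares of 225Ac were 0.602 (0.498 to 0.729) times that of 90Y and 0.628 (0.540 to 0.729) times that of 177Lu, and both went inside the size rule without the Lef1-led sub-cluster (0.818 and 0.838), the second also at the higher resolution (0.825). CD8 T shares were 0.346 (0.273 to 0.438) and 0.718 (0.575 to 0.892) times those groups, against 0.870 and 1.16 with the marker gate, and the second was 1.35 when EBRT and 90Y were left out of the clustering. The CD8 T share of 90Y was 2.07 (1.69 to 2.53) times that of 177Lu, and 1.33 with the marker gate, while their Treg ratio was 1.04 (0.881 to 1.23), and 0.959 at the lower resolution. The median over all genes was 0.17 in B cells between 225Ac and 177Lu.

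CD8 T cells of 225Ac had Irf7 at 3.85 times (2.10 to 7.43) the 90Y level and 3.03 times (1.78 to 5.30) the 177Lu level. Against 90Y their cytotoxic effector median was 0.54 with 5 of 13 higher, Gzmb at 2.45 times (2.06 to 2.92) and Ifng at 1.55 times (1.12 to 2.16). Their proliferation median was 0.95 with 11 of 19 higher, Mki67 at 2.45 times (1.68 to 3.61), but 0.33 with the 2 unnamed sub-clusters counted as CD8 T and 0.37 with equal doublet removal. Against 177Lu the proliferation median was 0.31 with 5 of 19 higher, Birc5 at 1.56 times (1.13 to 2.16), and it was -0.41 when EBRT and 90Y were left out of the clustering and -0.09 with equal doublet removal. In Treg the proliferation median was -0.76 against 90Y with 11 of 20 lower, Mcm5 at 0.492 (0.319 to 0.747), and -0.17 against 177Lu with 2 of 20 lower, Stmn1 at 0.664 (0.534 to 0.819). Interferon gamma genes of macrophages had medians of 0.82 against 90Y (14 of 18 higher) and 0.51 against 177Lu (8 of 18 higher), with Gbp5 at 2.24 times (1.60 to 3.18) and 1.89 times (1.44 to 2.51). Cxcl9 was the lower member in both, at 0.573 (0.491 to 0.668) and 0.343 (0.301 to 0.390).

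Between 90Y and 177Lu, CD8 T cells of 90Y had a type I interferon median of -0.39 with 1 of 10 lower, Ifi27l2a at 0.539 (0.477 to 0.608). Their cytotoxic effector median was -0.48 with 5 of 13 lower, Ccl3 at 0.108 (0.0808 to 0.141) and Ifng at 0.594 (0.440 to 0.797), and their proliferation median was -0.44 with 5 of 18 lower, Mki67 at 0.479 (0.329 to 0.687). Treg of 90Y had a proliferation median of 0.60, above all matched lists, with 10 of 20 higher, Mki67 at 1.92 times (1.59 to 2.32). Their type I interferon median was -0.45 with 3 of 17 lower, among them Ifit3, with 1 UMI in 90Y and a ratio of 0.0988 (0.00239 to 0.611). In macrophages the type I interferon median was -0.12 with 4 of 27 lower, Rsad2 at 0.547 (0.463 to 0.643), and 1 higher, Oas3 at 1.56 times (1.14 to 2.14).

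TCR libraries were compared for clonal expansion, the growth of single T cell families that share a receptor. They held 1207 cells in ICI, 617 in EBRT, 721 in 90Y, 1572 in 177Lu and 1209 in 225Ac, and values are means over 1000 draws of 617 cells with the central 95% of draws, except for EBRT, which was used whole. Clonotypes of 2 or more cells took 49.3% (47.2 to 51.2) of cells in 90Y, 41.0% in EBRT, 38.8% (35.0 to 42.6) in 177Lu, 31.5% (28.2 to 34.8) in ICI and 20.5% (17.3 to 23.3) in 225Ac. Clonotypes of 5 or more cells took 28.4%, 16.5%, 18.7%, 15.3% and 2.83% in the same order. The 10 largest clonotypes took 29.2% in 90Y, 13.9% in EBRT, 18.7% in 177Lu, 16.9% in ICI and 6.87% in 225Ac. The inverse Simpson index, the effective number of equally large clonotypes, was 48.6, 234, 127, 105 and 437 in this order. Clonotypes numbered 375 (366 to 384), 438, 440 (422 to 457), 471 (455 to 487) and 539 (526 to 551), the Gini index of inequality was 0.370, 0.262, 0.269, 0.226 and 0.119, and the normalised Shannon index of evenness was 0.887, 0.961, 0.942, 0.944 and 0.988.

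The largest ICI clonotype held 101 cells, with the TRB junction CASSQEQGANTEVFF, and the largest 177Lu clonotype held 85 cells, with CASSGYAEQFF. In 90Y the 2 largest clonotypes, of 67 and 66 cells, had the same TRB junction, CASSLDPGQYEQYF, while the largest held 13 cells in EBRT and 9 in 225Ac. In EBRT, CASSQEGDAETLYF was shared by clonotypes of 13 and 9 cells. In 177Lu, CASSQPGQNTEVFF was shared by clonotypes of 71 and 15 cells, together more than the 85 of the largest. Of the TRB junctions, 3141 were found in 1 library, 69 in 2, 13 in 3, 5 in 4 and 3 in all 5: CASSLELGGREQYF, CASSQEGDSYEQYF and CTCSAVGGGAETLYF. Both chains were recovered in 86.4% of ICI cells, 57.9% of EBRT cells, 63.8% of 90Y cells, 72.4% of 177Lu cells and 75.2% of 225Ac cells. Several measures moved by over 1.5 times when clonotypes were defined another way, which also changed the draw to 560 cells for merged and 357 for paired clonotypes, or were not drawn. With merged TRB junctions the inverse Simpson index was 21.5 in 90Y and 139 in EBRT, with paired clonotypes it was 128 in EBRT and 254 in 225Ac, and without drawing it was 667 in 225Ac. The 225Ac share in clonotypes of 5 or more cells was 1.88% with paired clonotypes, 4.48% with merged junctions and 9.02% without drawing, and its share in clonotypes of 3 or more cells was 10.8%. Paired clonotypes numbered 274 in ICI, 228 in EBRT, 215 in 90Y, 262 in 177Lu and 308 in 225Ac, and without drawing the deposited clonotypes numbered 856 in ICI, 960 in 177Lu and 988 in 225Ac.

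**Figure D4:**
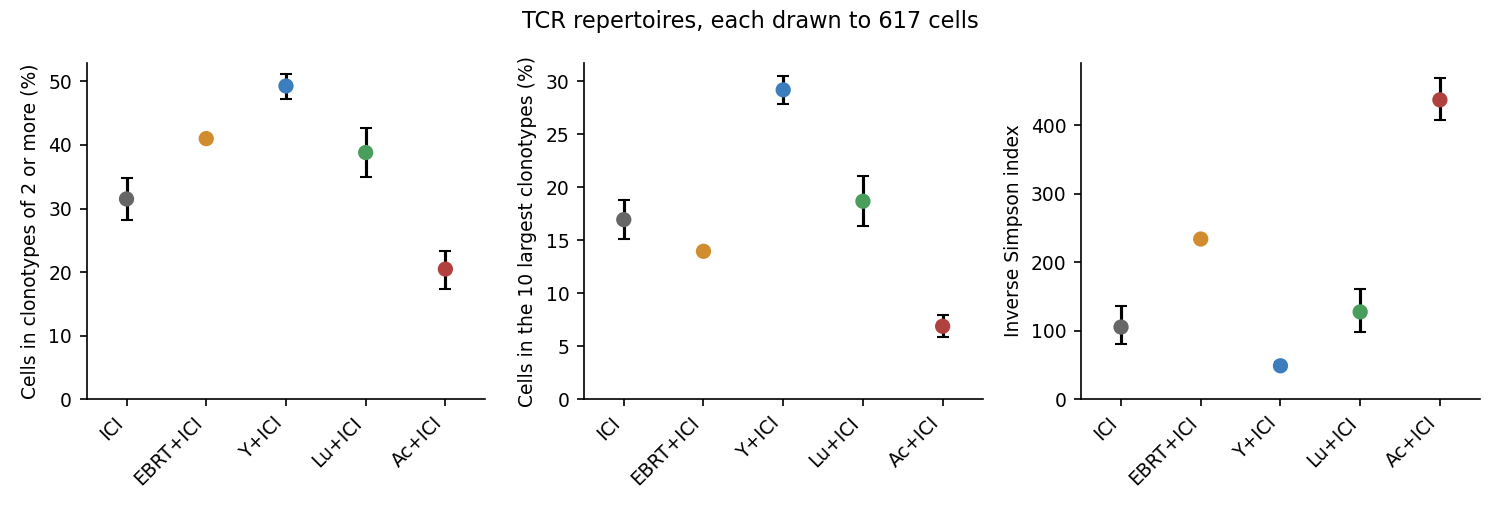
Points show the percentage of cells in clonotypes of 2 or more cells, the percentage in the 10 largest clonotypes and the inverse Simpson index in each group after drawing to 617 cells, and bars show the central 95% of draws. Expansion runs from 20.5% of cells in 225Ac to 49.3% in 90Y.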

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

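No tests were run for the values of this part, and no biological or technical explanation of them was tested. The deposited clonotype tables hold 2 columns that the comparisons do not use, which mark clonotypes by gene or junction evidence for mucosal-associated invariant T (MAIT) cells and invariant NKT (iNKT) cells, both innate-like T cell types. They stood out because each share lies above the limit that a count of 0 would allow, 0.486% in the smallest library. MAIT evidence was present in 15.7% of TCR cells in ICI, 16.4% in EBRT, 14.01% in 90Y, 23.5% in 177Lu and 21.3% in 225Ac. For iNKT evidence the shares were 11.3%, 13.3%, 13.9%, 11.3% and 14.6% in the same order. All cells with MAIT evidence had it on the TRB chain alone, and so did most with iNKT evidence, 132 of 136 in ICI, 80 of 82 in EBRT, 98 of 100 in 90Y, 170 of 178 in 177Lu and 174 of 176 in 225Ac. Evidence on both chains was recorded in 1 iNKT cell of ICI and 1 of 225Ac, and no cell had junction evidence, so these columns do not identify either cell type.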

How the results depend on the processing

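Alternatives chosen after seeing the data were the 25% mitochondrial limit, the 3 changes of denominator or pool, the unnamed sub-clusters 5 and 10 counted as CD8 T, the clustering without EBRT and 90Y, the single macrophage clusters, the lists in melanoma cells and the T and NK pool and, for lists, equal doublet removal and reduced totals. With 1 pool per group, no analysis could be paired or leave a library out. Over 456 values examined, 1969 alternative values stayed within the counting interval or spread of the main value, 368 moved beyond it and 34 reversed. The 277 gene levels were not tried with equal doublet removal, the 25% limit or single clusters. None reversed elsewhere: 268 stayed with TMM factors, 273 with reduced totals, 270 with doublets kept and 214 with cells weighted equally. For 116 list medians, 111 stayed with TMM factors, 110 with reduced totals and 110 with all members detected. All 28 share ratios stayed with doublets put back. Fewer stayed in other settings: with equal doublet removal 64 list medians stayed, 29 moved and 18 reversed, with cells weighted equally 83, 32 and 1, with the 25% mitochondrial limit 95, 17 and 4, with members of at least 100 UMIs 87, 13 and 1, in cluster 12 alone 10, 16 and 2 and in cluster 14 alone 7, 20 and 1. With sub-clusters 5 and 10 they were 13, 7 and 1, and clustered without EBRT and 90Y 34, 6 and 2. Of share ratios, 2 stayed, 10 moved and 2 reversed with the marker gate, 0, 8 and 0 without barcodes low in nuclear RNA, 2, 6 and 0 among leukocytes, 18, 10 and 0 with the stricter filter, 22, 6 and 0 without sub-cluster 2 or at resolution 2, 23, 1 and 0 at resolution 0.5, 24, 3 and 1 with equal doublet removal and 23, 4 and 1 with the 25% limit. For 8 of 10 ratios each, sub-clusters 5 and 10 or the clustering without EBRT and 90Y made no such change. Gene levels were not compared for CD8 T cells of EBRT (63 cells) and B cells of EBRT and 90Y (32 and 19).

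In this paragraph values are ratios of shares to ICI unless another group is named, and the cause was not tested unless the setting itself shows it. With the marker gate the CD8 T ratio was 0.804 for EBRT, 0.986 for 90Y and 0.742 for 177Lu, and 1.07 for 225Ac against EBRT, and those of 90Y and of 225Ac against EBRT reversed. The stricter filter gave Treg 2.37 for EBRT and B cells 0.0303, 0.0317, 0.160 and 2.04 for EBRT, 90Y, 177Lu and 225Ac. The 25% mitochondrial limit gave B cells 1.17, 0.130, 0.366 and 2.53 in that order, with EBRT reversed, by its construction adding cells of the libraries with most mitochondrial UMIs. Without barcodes low in nuclear RNA the B ratios were 0.0621, 0.0306, 0.172 and 1.37. Among leukocytes B cells were at 0.220 for EBRT, 0.257 for 177Lu and 1.31 for 225Ac. Equal doublet removal reversed macrophages of EBRT (1.51). The CD8 T ratio of 90Y was 1.53 at resolution 0.5 and 1.43 with sub-clusters 5 and 10, and the Treg ratio of 177Lu was 1.30 at resolution 2. Clustering without EBRT and 90Y gave CD8 T of 225Ac 1.13, and the pool without sub-cluster 2, the Lef1-led one, gave its Treg 1.22.

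Values in this paragraph are median log2 ratios of lists against ICI unless another group is named, and the cause was not tested. Equal doublet removal changed macrophage type I interferon to 0.15 in EBRT, 0.19 in 90Y, 0.39 in 177Lu and 1.45 in 225Ac, and macrophage proliferation to 0.82, 0.95, 1.14 and -0.0392, with type I interferon reversed in 90Y and proliferation reversed in EBRT, 90Y and 177Lu. It reversed macrophage MHC class II in EBRT (-0.0871), 90Y (-0.36) and 177Lu (-0.0320), CD8 T proliferation in 90Y (0.21) and in 225Ac against 177Lu (-0.0914), Treg proliferation in 225Ac (0.41), and macrophage chemokines (0.000555) and erythroid transcripts (3.91) in 225Ac. In melanoma cells it reversed type I interferon in EBRT (0.45), 90Y (0.13) and 177Lu (0.57) and proliferation in 90Y (0.16), 177Lu (0.80) and 225Ac (0.29). The 25% mitochondrial limit gave macrophage proliferation -1.003 in EBRT and -0.97 in 90Y and macrophage type I interferon 0.34 in 177Lu and 1.51 in 225Ac against EBRT. It reversed inflammatory macrophage genes in EBRT (0.0495) and Treg proliferation in 90Y (-0.27), and in 177Lu (0.60) and 225Ac (0.44) against EBRT. Members of at least 100 UMIs gave macrophage type I interferon -0.79 in EBRT, -0.0883 in 177Lu, and 0.23 in 90Y and 0.40 in 177Lu against EBRT, Treg type I interferon -0.16 in 90Y against 177Lu, and reversed macrophage interferon gamma in EBRT (-0.52). Equal weights gave macrophage proliferation -0.93 in EBRT and -0.56 in 177Lu, macrophage type I interferon 1.09 in 225Ac against EBRT and Treg type I interferon 1.35 and 1.08 in 225Ac against 90Y and 177Lu, and reversed Treg proliferation in 90Y against EBRT (-0.26).

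With macrophage cluster 12 alone, which holds part of the class by construction, type I interferon was -0.36 in 90Y, -0.15 in 177Lu and 0.94 in 225Ac, and 1.06 and 1.02 in 225Ac against 90Y and 177Lu. Proliferation was -0.69, -0.52 and -0.70 in 90Y, 177Lu and 225Ac, and MHC class II in 90Y (-0.0878) and erythroid transcripts in 225Ac (0.13) reversed. With cluster 14 alone, proliferation was -0.59, -0.59 and -0.75 in the same groups, type I interferon was 1.49 in 225Ac, and 1.62 and 1.44 against 90Y and 177Lu, and erythroid transcripts in 90Y reversed (-4.02). With sub-clusters 5 and 10 as CD8 T, type I interferon in 177Lu was 0.00219 and the stem-like list in 90Y reversed (-0.22). Clustering without EBRT and 90Y gave Treg type I interferon 1.55 in 225Ac and reversed CD8 T proliferation in 225Ac against ICI (-0.34) and against 177Lu (-0.41). The cause was not tested.

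For TCR cells in expanded clonotypes, the percentage was 37.3% in ICI, 50.8% in 177Lu and 26.9% in 225Ac without drawing, where larger samples by construction hold more expanded clonotypes. Counted from 3 cells it was 22.6%, 28.7%, 37.6%, 26.8% and 10.8% in ICI, EBRT, 90Y, 177Lu and 225Ac, by construction lower. Paired clonotypes, drawn to 357 cells, gave 52.4% in EBRT and 52.0% in 90Y, and clonotypes merged by TRB junction, drawn to 560, gave 44.6% in EBRT, 54.3% in 90Y and 43.6% in 177Lu, for which the cause was not tested. In each of these settings that gave both values, 225Ac stayed below ICI. A first look covered 461 list medians with 3542 alternative values, of which 71 reversed, and 162 share ratios with 1373, of which 41 reversed.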

Other observations

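Melanoma cells and the whole T and NK pool were added to the list comparisons after the data were seen. Type I interferon genes of melanoma cells had a median log2 ratio against ICI of 1.21 in 225Ac, with 22 of 27 members higher, and of -0.74 in EBRT, -0.90 in 90Y and -0.41 in 177Lu, with 14, 19 and 7 members lower. Isg15 was at 254 CPM in 225Ac and 55.9 CPM in EBRT against 112 CPM in ICI, and Ifit3 in 225Ac at 4.56 times (4.31 to 4.82) its ICI level. Interferon gamma genes of melanoma cells had a median of 0.69 in 225Ac with 10 of 19 higher and 1 lower. Proliferation genes had medians of -1.67, -1.22, -0.52 and -0.93 in EBRT, 90Y, 177Lu and 225Ac, with 18, 17, 6 and 17 of 20 lower, and Mki67, a marker of dividing cells, was at 0.278 (0.262 to 0.295) of its ICI level in EBRT and 0.514 (0.492 to 0.538) in 225Ac. With equal doublet removal the type I interferon medians were 0.45, 0.13, 0.57 and 2.10, the proliferation medians -0.30, 0.16, 0.80 and 0.29, and the interferon gamma median 1.40. The class medians mix level with composition: the melanoma cluster led by Ifit3 held 443 of 2897 cells in 225Ac and 162 of 3690 in ICI, and the one led by cell cycle genes 662 in ICI and 141 of 2998 in EBRT.

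In the T and NK pool the stem-like and memory list had medians of -0.55 in EBRT, -1.15 in 90Y, -0.80 in 177Lu and 0.34 in 225Ac. The naive T cell genes Lef1 and Ccr7 were at 0.422 (0.349 to 0.508) and 0.421 (0.358 to 0.493) of their ICI levels in 90Y and at 0.446 (0.391 to 0.509) and 0.335 (0.296 to 0.379) in 177Lu. In EBRT, Ccr7 was at 0.659 (0.559 to 0.774) and Satb1 at 2.14 times (1.90 to 2.41). In 225Ac, Lef1 was at 1.80 times (1.63 to 1.98), and type I interferon genes of the pool had a median of 1.40 with 27 of 27 higher, Isg15 at 2.96 times (2.72 to 3.23). This value includes an unnamed sub-cluster led by Ifit3 and Isg15, outside the CD8 T and Treg classes, that held 11.1% of the pool in 225Ac and 2.42% in ICI. TRA junctions ending in DYSNNRLTL, noticed after the sequences were seen, were found in 20.4% (18.1 to 22.96) of the ICI cells with a TRA chain, 6.04% in EBRT, 2.98% in 90Y, 15.4% in 177Lu and 6.83% in 225Ac, across 37, 8, 9, 27 and 28 clonotypes with 37, 9, 9, 25 and 24 different TRB junctions. Of clonotypes with a TRA chain these were 4.95%, 2.92%, 3.00%, 3.66% and 3.70%, so the difference by cells rests largely on expansion, and 1 ICI clonotype held 101 of the 223 cells.

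Of the tests below, those of scaling, unequal doublet removal and the mitochondrial limit in macrophages were chosen after their results could be seen. Type I interferon genes were higher in 225Ac than in ICI in CD8 T cells, Treg, B cells, macrophages, melanoma cells and the T and NK pool. RNA or doublets from another class tried would need 28.4 times the share that marker genes allow in Treg, the highest value. It would need 21.6 times in macrophages, 19.6 in melanoma cells, 16.3 in CD8 T cells and 1.52 in B cells. In B cells several classes together were not excluded. Non-mature dendritic cells were not tried as sources, nor other T and NK cells for Treg and CD8 T cells. Free RNA of 1 unnamed source would keep its genes in a common ratio, from which 17 of 27 members lay over 1.5 times away. A few abundant genes were argued against by the lowest median under the other scalings, 0.74, in CD8 T, Treg, B cells and macrophages. Differences in handling between pools stay open, because each group is 1 library. That the alpha emitter raises the interferon response is a hypothesis that more libraries could test.

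B cells took larger shares in ICI and 225Ac than in EBRT, 90Y and 177Lu. So did Lef1-led T cells, except that 11.1% in ICI and 8.81% in EBRT lay within the size rule. Loss of B cells to the mitochondrial limit may account for EBRT. Without that limit the ratio of barcodes with B cell markers to ICI was 0.844, and 5.44% above it had these markers against 1.47% below. This loss was argued against in 90Y and 177Lu, with ratios of 0.123 and 0.405. Lymph node tissue was not decided, since Ccl21a, Madcam1 and Glycam1 disagreed (lowest summed ratio 0.671). Madcam1 had 8 and 16 UMIs in ICI and 225Ac against 1, 0 and 6 in EBRT, 90Y and 177Lu. Glycam1 had 7 and 1 against 0, 2 and 1, and Ccl21a 14 and 8 against 17, 20 and 46. A difference between treatments remains untested.

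Proliferation genes were lower in macrophages of the 4 radiation groups than in ICI. Doublets with tumour cells left in ICI were argued against, needing 21.5 times the melanoma RNA that Sox10, Mitf and Ptgds allow. The 25% mitochondrial limit moved the medians of EBRT and 90Y further below 0, to -1.003 and -0.97. Most EBRT barcodes (median 33.2%) stayed above that limit, so loss to the filter was not decided there. In 90Y (median 14.5%) the move argued against loss of cells of up to 25%. Unequal removal of macrophages with high doublet scores may account for the pattern: with the same share removed everywhere the lowest median was -0.0392, and 832 of 1139 ICI macrophages left the class, with proliferation transcripts at 2559 CPM against 968 CPM in those that stayed. Whether the removed cells were dividing macrophages or doublets cannot be settled here, and a difference between treatments stays open.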
